A study of Mus musculus with 22 samples.

How the data were processed

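The data are 22 poly-A RNA libraries, sequenced as read pairs of 150 bases, from liver (5 air, 5 benzene) and lung (6 air, 6 benzene). The submitters' notes name fastp 0.20.0, STAR and edgeR 3.10 with the genome build GRCm38; the read counter, the annotation and the filter on low genes are not given in the sources used here. The deposited tables hold 1 value per gene and library as normalized signal, headed CPM by the authors. Every value is a whole number of reads, within a tolerance of 0.01, over 1 factor per library, and the factors equal those of edgeR's RLE method over all genes of each table (largest difference 0%). The deposited change column, recorded here as log2 and headed a log fold change by the authors with no base given, was computed by them from the same comparison of benzene with air. Its slope on the log2 ratio of the group means is 0.504 in liver and 0.503 in lung, not the 1 of a log2 value, so its base is in doubt and it was not used. The deposited p-value by the authors is unadjusted. In liver the deposited benzene mean equals the mean of a gene and the gene listed before it in 12258 of 12259 genes, within a relative tolerance of 1e-06, so it was not used. Values, groups and changes here come from the library columns. The plan had assumed raw counts, and the unit turned out otherwise, so the test it named for normalized values was used.

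Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from what is said here to have been chosen later. Genes were matched by identifier to GENCODE M21, 12255 of 12259 in liver and 15955 of 15971 in lung. Genes with a value of at least 1 in 5 liver or 6 lung libraries were kept, values were taken as log2(value + 1), and groups were compared by limma-trend (limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjusted p under 0.05. The difference between tissues was the contrast of both responses in 1 fit over genes in both tables. Of 74 gene lists, those with at least 5 tested members were tested by camera with a preset correlation of 0.01, two-sided. Overlaps were tested by Fisher's exact test. After adjusting the deposited p, 163 liver genes and 860 lung genes pass, of which 156 and 818 are also past the threshold by limma in the same direction.

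The rule for named genes takes, per tissue, the 8 highest and 8 lowest changes past the threshold with a group mean of at least 1, leaving out predicted genes, clone names, pseudogenes and immunoglobulin segments; up to 4 members of each passing list and 2 of any list with members past the threshold; 10 genes of benzene metabolism and stress whatever their result; and 5 genes per direction of the difference between tissues. It gives 71 genes in liver and 134 in lung. The text prints 41 and 48 of these, a subset picked after the values were seen.

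The alternatives were other scalings, tools (edgeR 4.0.16, DESeq2 1.42.0, limma-voom), filters, a pseudocount of 0.1, a minimum change, a replicate block, all 22 libraries in 1 fit, other list tests and leaving out each library. TMM scaling, edgeR, array weights, robust eBayes and the tests without lung air replicate 5 were added after the data were seen. Each comparison was repeated on 100 splits of its libraries, the real one included. The tests were tried on simulated data: of unchanged genes, 7 of 11577 were called in liver and 4 of 15318 in lung. The simulated libraries and genes were drawn independently, with no outlying library and no shared RNA source. These counts, and the recovered shares given below, do not cover such cases. Reads are not deduplicated by molecular identifiers, so the floor of 3 reads covers counting error only. No library was left out of the main tests. Results without lung air replicate 5, such as the correlations of immunoglobulin variable genes, are named as such. Tables were made with Python 3.11.15 and pandas 2.3.3.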

Results

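Poly-A RNA was sequenced from liver and lung of male C57BL/6J mice, 14 weeks old, that had breathed benzene or filtered air. Benzene is a solvent that enzymes in liver and lung oxidise to reactive products. The exposure was 50 ppm for 6 hours a day on 5 days a week over 6 weeks. The liver set had 5 air and 5 benzene libraries, and the lung set had 6 of each. Recovered reads per library ran from 9.46 to 12.42 M (mega) in liver air, 9.71 to 12.71 M in liver benzene, 8.3 to 11.92 M in lung air and 8.4 to 10.02 M in lung benzene. Levels are normalized CPM, given as mean ± SD, and changes are benzene over air on log2(CPM + 1) ± SE, a scale that understates changes of genes near 0. The labels number the samples and do not say that each came from a separate animal, so the p-values may measure technical spread. Lung air replicate 5 stood apart from the other lungs, with 894 genes without a read where the other 5 air lungs had 17 to 61.

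The liver comparison asked which transcripts differed after benzene. Macrophage genes were higher in benzene livers. Lyz2, the macrophage lysozyme, rose from 13.7 ± 2.03 to 29.4 ± 3.36 (n = 5 and 5), and Cd5l, a protein secreted by tissue macrophages, from 22.7 ± 2.36 to 47.2 ± 7.32. The scavenger receptor gene Marco rose from 2.95 ± 0.456 to 7.71 ± 0.925. Genes with sex-biased liver expression also moved: Cyp2a4, a steroid hydroxylase higher in females, fell from 7.93 ± 1.76 to 0.467 ± 0.188, and Mup20, a urinary pheromone protein made by males, rose from 2580 ± 115 to 4020 ± 766.

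Of 11968 genes tested in liver, 186 passed an adjusted p of 0.05, 98 higher and 88 lower with benzene. The gene with the largest rise was Chil4, a chitinase-like protein (ENSMUSG00000063779, chromosome 3, 106201490 to 106219507 in GRCm38). It had no read in the 5 air livers and 13.7 ± 1.66 in the benzene livers, at least 245-fold higher than the floor of 3 reads over the air group, a bound that covers counting error only. Dmbt1, a mucosal scavenger receptor, rose from 0.227 ± 0.196 to 6.66 ± 2.2 (adjusted p = 1.79e-06). Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 109 ± 10.5 to 402 ± 38.9 (change 1.87 ± 0.0843, adjusted p = 2.89e-10, 5 of 5 benzene libraries above every air library). The nuclear receptor gene Nr4a1 rose by 1.64 and the stress-response gene Gadd45g by 1.06 on the log2 scale. The lowest changes after Cyp2a4 were those of Mmd2 (-1.23), the transcriptional repressor gene Bcl6 (-1.19, adjusted p = 4.18e-06), the nuclear noncoding RNA Malat1 (-1.08), Nipal1 (-1.08), Lars2 (-1.07), the glutathione transferase gene Gstm3 (-1.06) and the histone methyltransferase gene Suv39h2 (-1.04). Nipal1 missed the threshold without air replicate 2 (adjusted p = 0.0727), 3 (0.0642) or 4 (0.0787) or benzene replicate 1 (0.0675) or 5 (0.0667), and Suv39h2 missed it without air replicate 5 (0.0539). Lars2 missed it with edgeR (adjusted p = 0.0678) and with robust eBayes (0.0773). With all 22 libraries in 1 fit, Malat1 (0.0736), Nipal1 (0.166), Lars2 (0.0712) and Suv39h2 (0.053) missed it.

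Of 53 gene lists tested in liver, 13 passed, 9 ranked higher and 4 lower, and 8 of them held with an estimated correlation between genes. Of 18 Kupffer cell markers, genes of resident liver macrophages, 10 rose and 0 fell, or 15 adjusted over the list alone. The list adjusted p was 1.19e-22 by camera with the preset correlation, 0.00513 with an estimated correlation and 0.028 by exact permutation of list means. That permutation value is the lowest the test gave in liver. Other lists such as cholesterol synthesis share it, so it does not rank lists by strength. Of 20 monocyte and macrophage markers, 6 rose, or 16 adjusted over the list alone, among them the complement gene C1qb (0.81) and the protease gene Ctss (0.75). Of 25 genes of interferon gamma and antigen presentation, 5 rose, or 12 adjusted over the list alone. They included Cd74, the invariant chain, from 34 ± 5.78 to 60.7 ± 7.37, and the class II gene H2-Eb1 from 14.3 ± 1.43 to 24.7 ± 2.67. The 33 interferon-stimulated genes ranked higher as a list, with 0 genes past the threshold by limma, 0 by edgeR and 3 higher at an unadjusted p under 0.05. The means of the macrophage lists and of the antigen presentation list were each higher in 5 of 5 benzene livers than in every air liver.

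Of 28 male-biased liver genes, 8 rose and 0 fell, or 15 rose and 1 fell adjusted over the list alone, with Selenbp2 from 496 ± 37.0 to 863 ± 109. Of 13 female-biased genes, 3 fell, or 5 adjusted over the list alone, with the steroid enzyme gene Cyp17a1 falling from 6.39 ± 1.37 to 2.61 ± 0.722. Mup and Cyp2a genes are near-identical copies whose reads can be shared. The 26 cholesterol synthesis genes ranked lower, with 0 past the threshold by limma, 1 by edgeR, 11 lower at an unadjusted p under 0.05 and 4 lower adjusted over the list alone. Of 12 mitochondrially encoded transcripts, 2 fell, or 6 adjusted over the list alone, and their share of reads was 3.88% to 4.59% in air and 2.18% to 3.73% in benzene livers. One of them, mt-Nd4, fell from 3610 ± 189 to 2230 ± 690 (adjusted p = 0.0398). That call was lost without air replicate 1 (0.0539), 2 (0.122), 3 (0.0956), 4 (0.0951) or 5 (0.1) or benzene replicate 1 (0.0565) or 5 (0.111), with edgeR (0.21), with robust eBayes (0.188) and with all 22 libraries in 1 fit (0.556).

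Of 26 genes of gluconeogenesis and glucose handling, 2 rose and 4 fell, or 4 rose and 8 fell adjusted over the list alone (adjusted p = 0.134 with an estimated correlation). Got1, a transaminase, fell by 0.72 on the log2 scale, and G6pc, the last enzyme of glucose release, rose by 0.47. Pck1, an early enzyme of the pathway, fell by 0.41, a call lost without air replicate 2 (adjusted p = 0.0649), 3 (0.0602), 4 (0.0595) or 5 (0.0539) and with all 22 libraries in 1 fit (0.37). Of 30 acute phase proteins, 3 rose, or 5 adjusted over the list alone (adjusted p = 0.0619 with an estimated correlation), with Orm2 and Saa1 higher by 0.79 and 0.75. Of 24 NRF2 target genes, 2 rose, or 5 adjusted over the list alone (adjusted p = 0.0518 with an estimated correlation). They were Hmox1, a haem-degrading enzyme, from 14.3 ± 0.985 to 27.5 ± 3.84, and Me1 (0.30), whose call was lost without air replicate 2 (adjusted p = 0.105), 3 (0.0871) or 4 (0.0916) or benzene replicate 1 (0.0605), 3 (0.067) or 5 (0.0731) and with all 22 libraries in 1 fit (0.28). The cholangiocyte and erythroid lists, 12 genes each, had 0 genes past the threshold by limma and by edgeR, with 4 and 3 higher at an unadjusted p under 0.05 and 0 and 1 higher adjusted over the list alone (list adjusted p = 0.0518 and 0.134 with an estimated correlation).

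Among enzymes that handle benzene or its products, Cyp2e1, the main benzene oxidase of liver, had 8160 ± 161 in air and 7900 ± 528 in benzene livers (adjusted p = 0.844). Cyp2f2, Cyp1a1, Ephx1, Nqo1 and Gstt1 did not pass either, with log2 changes from -0.28 to 0.17, though Gstt1 passed with array weights (-0.23, adjusted p = 0.0467). Cyp2b10 fell by 0.69, Gstm2 fell by 0.65 and the fatty acid hydroxylase gene Cyp4a14 fell by 0.69, and the clock repressor gene Nr1d1 fell by 0.60. The count of 186 moved with the library left out. It was 101, 105, 98 and 110 without air replicates 2 to 5, and 109, 131 and 113 without benzene replicates 1, 3 and 5. It was 271 without air replicate 1, 204 and 233 without benzene replicates 2 and 4, and 316 by DESeq2 with all libraries. On simulated changes the test recovered 34.7% of genes changed 1.5-fold and 79.6% of those changed 2-fold.

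**Figure D1:**
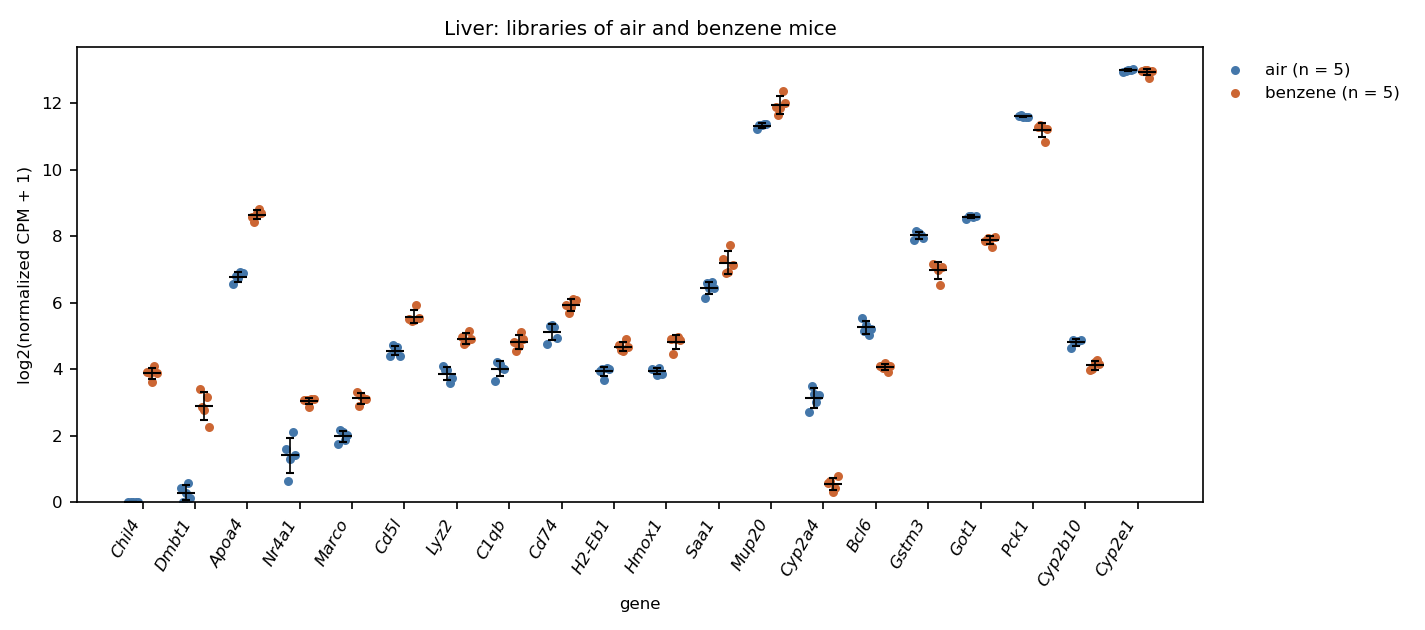
Liver levels of 20 genes named by rule, as log2(normalized CPM + 1), with 1 point per library and bars for the mean and SD of 5 air and 5 benzene libraries. Chil4 was at 0 in the 5 air livers, and Cyp2e1 did not pass the threshold.

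The lung comparison asked the same question of the organ that takes up the vapour. The genes that changed most included genes of keratinising epithelium and of muscle. Asprv1, a skin protease, rose from 13 ± 2.37 to 215 ± 12.2 (n = 6 and 6), and Rptn, a cornified envelope protein, from 10.9 ± 3.55 to 170 ± 10.03. Myh2, a myosin heavy chain of fast muscle fibres, fell from 107 ± 22.5 to 0.689 ± 0.338, and Myl2, a light chain of heart and slow muscle, from 20.9 ± 4.02 to 0.0836 ± 0.119. Immunoglobulin genes fell as well: Ighm, the IgM heavy chain, went from 489 ± 69.9 to 194 ± 8.29.

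Of 15706 genes tested in lung, 891 passed, 531 higher and 360 lower with benzene. The highest was Myh8, a myosin of developing and specialised muscle (ENSMUSG00000055775), from 0.897 ± 0.586 to 215 ± 11.8 (change 6.90 ± 0.194, adjusted p = 3.22e-11, 6 of 6 libraries above every air library). Serpinb12, Serpinb3a, Lce3a, the antimicrobial peptide gene Defb4 and the desmosome gene Pkp1 rose by 4.30, 4.28, 3.96, 3.81 and 3.71 on the log2 scale. Serpinb3 genes are close copies whose reads can be shared. In a list of stratified squamous epithelium genes written after the lung values had been seen, 39 of 42 rose and 0 fell. Its most abundant members, Krt13 and Krt4, were chosen after their values were seen. Krt13 had 131 ± 23.4 in air and 1570 ± 83.3 in benzene lungs, and Krt4 had 107 ± 21.5 and 1380 ± 50.3.

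Of 60 gene lists tested in lung, 25 passed, 4 ranked higher and 21 lower, and 11 held with an estimated correlation. Of 21 skeletal muscle genes, 13 fell and 1 rose, or 14 and 1 adjusted over the list alone. Myh4 fell by 2.05 on the log2 scale, and Pvalb, a calcium buffer of fast fibres, fell by 3.60. DESeq2 gave Pvalb no p, and its level in air replicate 5 was 230 against 40.4 to 54.0 in the other air lungs. Of 25 cardiac muscle genes, 15 fell and 1 rose, or 20 and 1 adjusted over the list alone, with the atrial peptide gene Nppa from 214 ± 35.3 to 75.5 ± 10.05 and Myh7 from 47.1 ± 5.6 to 19.0 ± 2.05. Myh7 is also among the skeletal muscle genes, so the counts of these lists are not independent. The slow-fibre genes Tnnt1, Ankrd2 and Tnni1 fell (log2 changes -2.69, -2.53 and -2.46).

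Of 19 plasma cell and constant immunoglobulin genes, 8 fell and 1 rose, or 11 and 2 adjusted over the list alone. Ighg2c fell by 3.03 and Igkc fell by 1.33 on the log2 scale. Of 30 B cell markers, 2 fell, also adjusted over the list alone. Of 31 genes of interferon gamma and antigen presentation, 6 fell, or 7 adjusted over the list alone, with H2-Ab1 from 732 ± 89.3 to 460 ± 49.9 and Cd74 from 1590 ± 269 to 1070 ± 77.9. Of 25 dendritic cell markers, 4 fell and 1 rose, or 8 and 1 adjusted over the list alone. Of 26 heat shock chaperones, 11 fell, or 20 adjusted over the list alone, with Dnaja1, Stip1 and Hspa1b lower (log2 changes -0.62, -0.70 and -0.61). The unfolded protein response list (5 of 31 fell, or 7 fell and 1 rose adjusted over the list alone), the cell cycle list (2 of 47 fell, 1 adjusted over the list alone, with the proliferation marker Mki67 falling by 0.68) and the ciliated cell list (3 of 29 fell, 11 adjusted over the list alone) also ranked lower. Mki67 missed the threshold with all 22 libraries in 1 fit (adjusted p = 0.0864). With air replicate 5 left out and an estimated correlation, the B cell, plasma cell and unfolded protein response lists missed the threshold (adjusted p = 0.0747, 0.0514 and 0.0643).

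Of 37 p53 target genes, 7 rose and 1 fell, or 10 and 1 adjusted over the list alone. Perp, a desmosome protein that squamous epithelia also express, rose from 48.1 ± 4.75 to 146 ± 7.48, and Trp53inp1 rose by 0.62 on the log2 scale. Cdkn1a, the p21 cell cycle inhibitor, rose from 79.7 ± 10.5 to 103 ± 2.34 (adjusted p = 0.0256). That call was lost without benzene replicate 1 (0.0701), 2 (0.0555), 3 (0.0666), 5 (0.0592) or 6 (0.0656). Of 26 alveolar macrophage markers, 6 rose and 3 fell, or 8 and 3 adjusted over the list alone (adjusted p = 0.113 with an estimated correlation), with Chil3 and Ear2 higher by 0.63 and 0.82. Arg1, an arginine-degrading enzyme, rose from 1.29 ± 0.696 to 10.01 ± 1.74. Of 26 club cell markers, 7 fell, or 10 adjusted over the list alone (adjusted p = 0.0555 with an estimated correlation), with Muc5b and Reg3g lower (-0.94 and -0.87). Of 22 neutrophil markers, 6 fell, or 10 adjusted over the list alone (adjusted p = 0.0932 with an estimated correlation), with Ltf and Lrg1 lower (-1.10 and -0.61). Of 31 cytokines, chemokines and adhesion molecules, 2 rose and 7 fell, or 4 and 10 adjusted over the list alone (adjusted p = 0.149 with an estimated correlation, and 0.0549 without air replicate 5). Ccl22 fell by 0.84, and Tgfb1 fell by 0.34, a call lost without benzene replicate 1 (adjusted p = 0.0512) and with all 22 libraries in 1 fit (0.108).

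Aldh3a1, an aldehyde dehydrogenase, rose from 84.3 ± 8.8 to 209 ± 9.03, while Cyp1a1, a classic target of the aryl hydrocarbon receptor, fell from 58.6 ± 35.7 to 21.2 ± 1.05. Cyp1a1 in air replicate 5 was 131, against 40.1 to 47.6 in the other air lungs. Nqo1, a quinone reductase, rose from 13.4 ± 2.88 to 20.4 ± 2.12 (adjusted p = 0.0214), and lost its call without benzene replicate 1 (0.0657), 2 (0.0531) or 6 (0.0639). Cyp2e1 had 102 ± 19.3 in air and 77.7 ± 2.61 in benzene lungs (adjusted p = 0.0876). It passed without air replicate 5 (7.62e-05), and with all lung libraries by DESeq2 (0.0209), in the fit of all 22 libraries (0.0395) and with array weights (5.02e-05). Cyp2f2, a benzene-oxidising enzyme of mouse lung, changed by 0.01 ± 0.259 (adjusted p = 0.991), and by -0.28 without air replicate 5 (adjusted p = 0.0341). Gstt1 was at 0.15 with all libraries and -0.19 without air replicate 5 (adjusted p = 0.0738), and Cyp2b10, Ephx1 and Hmox1 did not pass (-0.08, 0.28 and 0.22). The count of 891 was 2284 without air replicate 5, 502, 539, 536 and 534 without benzene replicates 1, 3, 5 and 6, and 1669 by DESeq2. On simulated changes the test recovered 31.2% of genes changed 1.5-fold and 75.0% of those changed 2-fold.

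**Figure D2:**
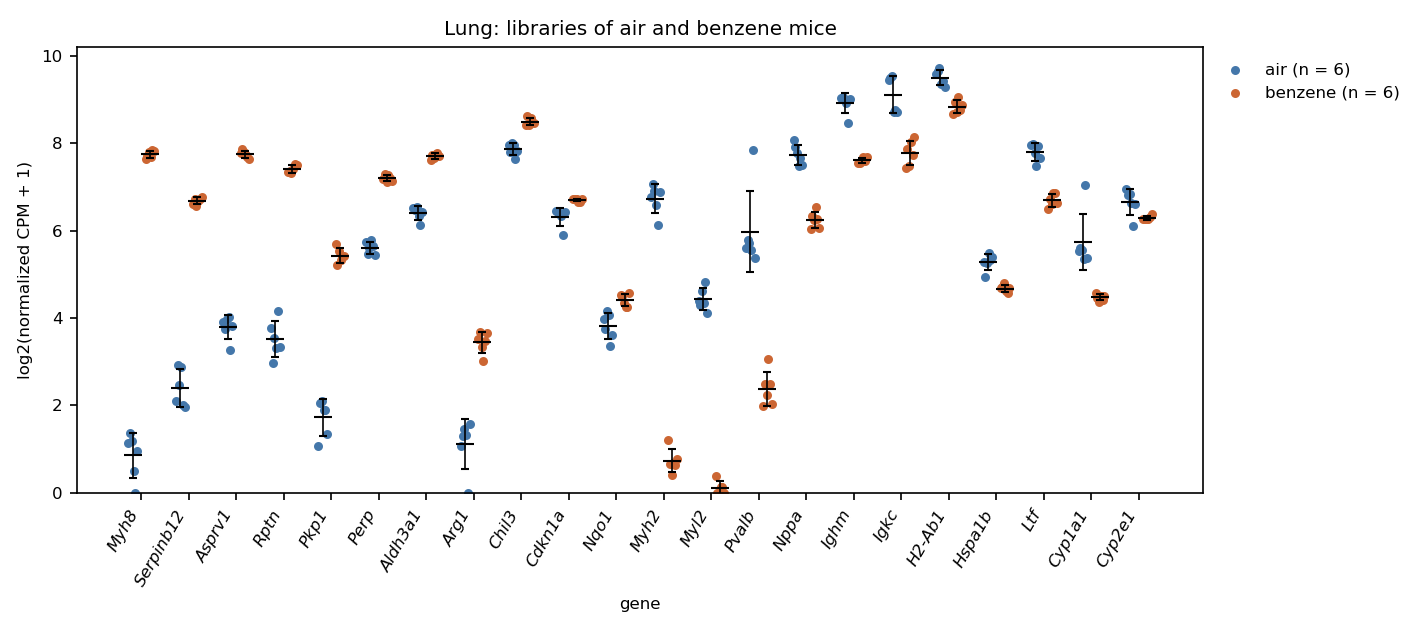
Lung levels of 22 genes named by rule, as log2(normalized CPM + 1), with 1 point per library and bars for the mean and SD of 6 air and 6 benzene libraries. Air replicate 5 is the high point of Pvalb (230 CPM) and of Cyp1a1 (131 CPM).

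**Figure D3:**
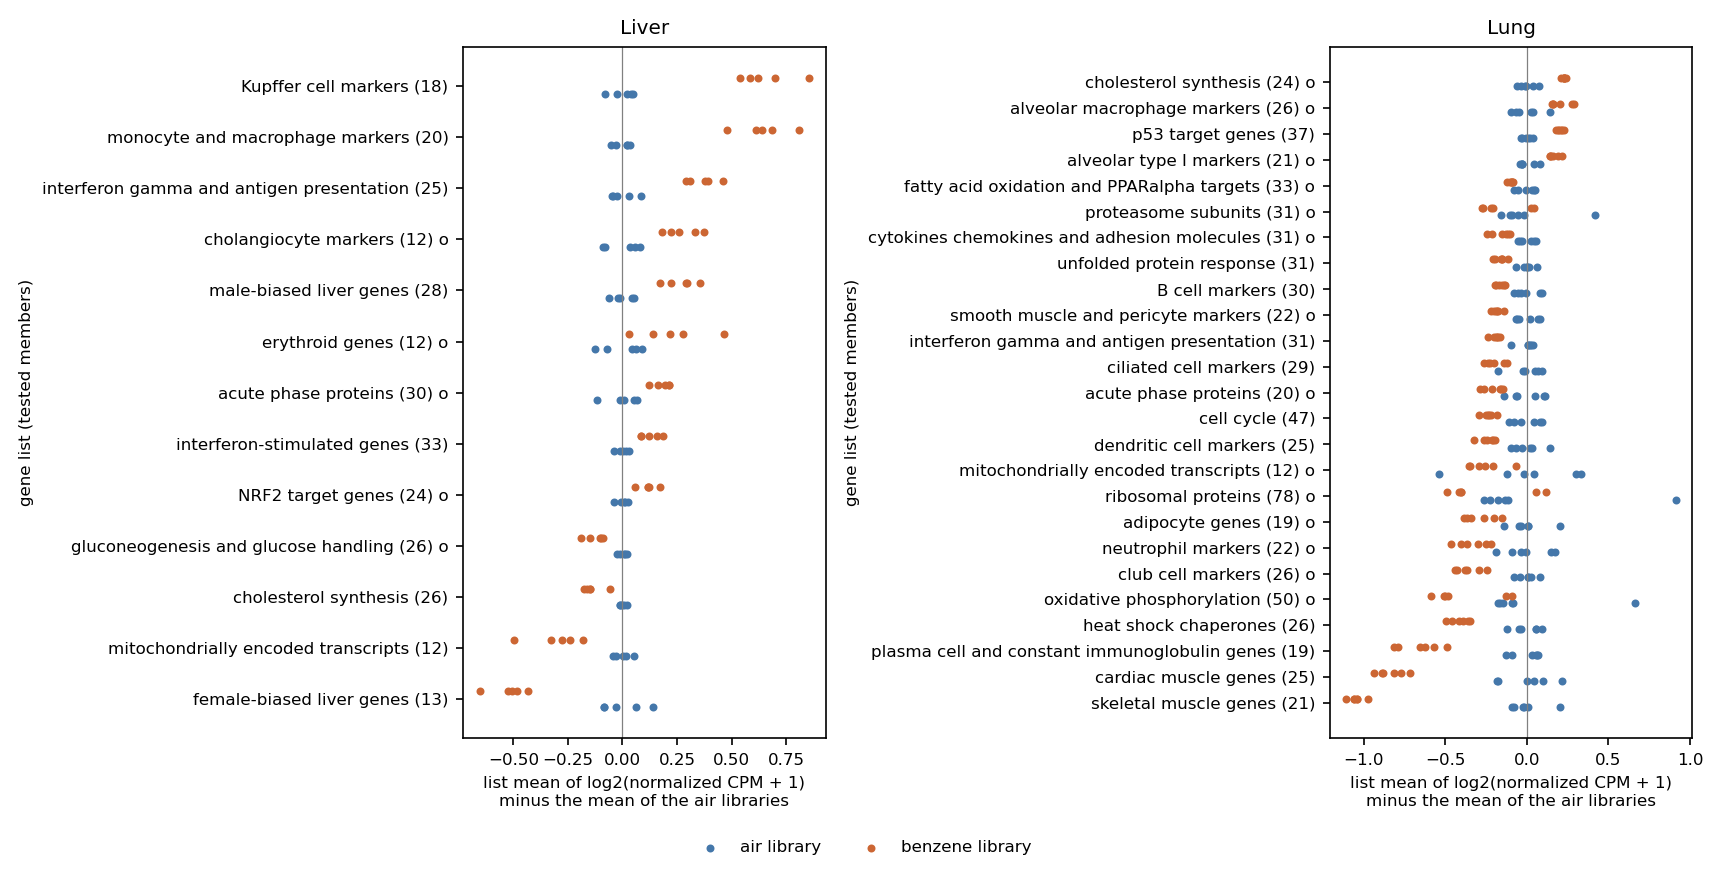
Mean log2(normalized CPM + 1) over the tested members of each list that passed, 13 in liver and 25 in lung, relative to the mean of the air libraries, with 1 point per library and the number of tested members in brackets. The mark o stands beside the lists that missed the threshold with an estimated correlation, which left 8 in liver and 11 in lung.

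The last comparison asked whether liver and lung responded differently. Response here means the change of benzene over air libraries, and its cause was not tested by this comparison. The tables were normalized separately, and each response was taken within its own table. Class II antigen presentation genes rose in liver and fell in lung. H2-Eb1 changed by 0.75 in liver and by -0.54 in lung (difference 1.29 ± 0.13, adjusted p = 8.43e-07), and the differences of H2-Ab1, H2-Aa and Cd74 were 1.39, 1.16 and 1.39. Several epithelial genes rose in lung, with differences of liver minus lung of -1.50 for Perp (adjusted p = 5.11e-09), -2.19 for Dsc2, -2.33 for Tgm1, -1.90 for Gjb2 and -1.73 for the fatty acid binding protein gene Fabp5. Ighm and Tnnt1, which fell in lung, had differences of 1.73 and 2.51.

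Of 11266 genes tested in both tissues, 159 differed, 81 with the higher response in liver and 78 with the lower, against 245 and 132 by DESeq2 and 88 and 56 by edgeR. Of genes past the threshold in each tissue, 3 were higher in both, where chance gave 1.28 (Fisher's exact test, two-sided, p = 0.137), and 2 were lower in both, where chance gave 1.14 (p = 0.315 by the same exact test). The first were Nr4a1, Trp53inp1 and Akr1c14, and the others Got1 and 8430408G22Rik. There were 7 higher in liver and lower in lung, where chance gave 1.1 (exact p = 0.000109): Gm20481, Cd74, H2-Eb1, C1qc, H2-Aa, Cfp and H2-Ab1. None was lower in liver and higher in lung, a count of 0 by limma and by edgeR, 8 at an unadjusted p of 0.01, 4 by DESeq2 and 5 without lung air replicate 5. Akr1c14, 8430408G22Rik, Gm20481, C1qc and Cfp were named after their values were seen. Genes are not independent, so these tests describe the overlap. The count of 159 was 103, 95 and 104 without liver benzene replicates 1, 4 and 5, 88, 102 and 99 without lung benzene replicates 1, 5 and 6, 327 without lung air replicate 5, and 377 by DESeq2. On simulated differences the test recovered 57.1% of those of 2-fold. With lung air replicate 5 left out, 11 genes were lower in both tissues, where chance gave 4.14 (odds ratio 3.02, exact p = 0.00246), and 8 were higher in both, where chance gave 4.19 (exact p = 0.0691). In that setting 10 were higher in liver and lower in lung, where chance gave 4.01 (odds ratio 2.79 against 7.23 with all libraries, exact p = 0.00613), and 5 were lower in liver and higher in lung, where chance gave 4.32 (exact p = 0.62). At an unadjusted p of 0.01, 20 were higher in both, where chance gave 10.2 (exact p = 0.00498), and 19 were higher in liver and lower in lung, where chance gave 9.5 (odds ratio 2.13, exact p = 0.0038). By DESeq2 12 were higher in liver and lower in lung, where chance gave 5.14 (odds ratio 2.52, exact p = 0.00526), and by edgeR 8, where chance gave 1.24 (odds ratio 7.45, exact p = 3.02e-05).

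**Figure D4:**
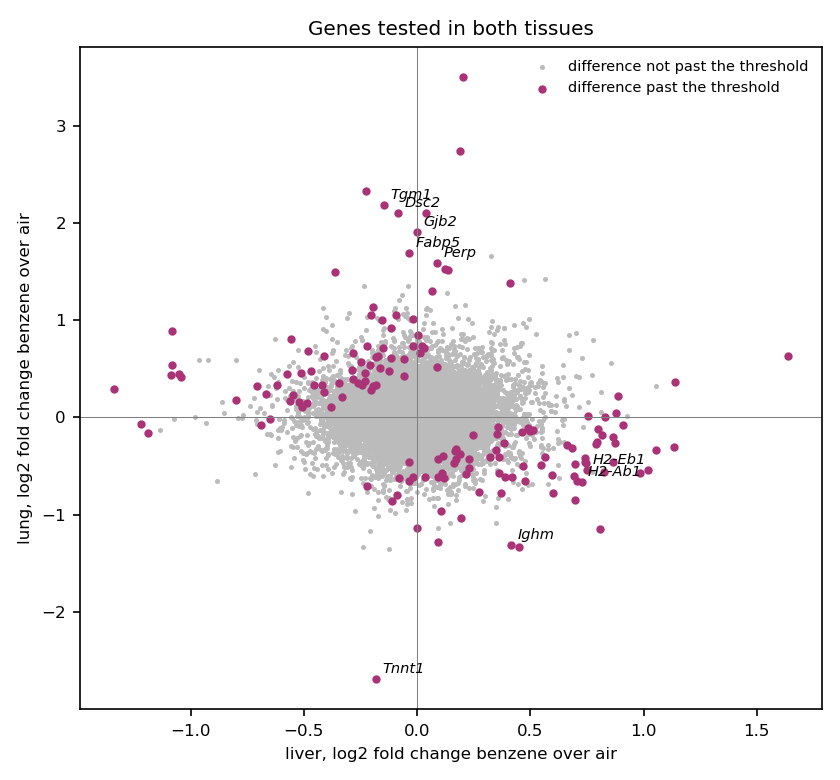
Log2 changes of benzene over air in liver (horizontal) and lung (vertical) for 11266 genes, with 1 point per gene. Coloured points are the 159 genes whose responses differed past the threshold.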

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

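The tests of immunoglobulin variable genes, of squamous and muscle genes, and of the label and source of lung air replicate 5 were chosen only after the result was seen.

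Of 194 groups of values checked, 34 held 1 library far from the rest of its group by Dixon's test, which chance gives in about 1 in 20 groups. In liver air, replicate 1 was far from the others for Got1 (367), Mup20 (2380), Cyp4a14 (459), Ephx1 (523) and Gstm2 (129), replicate 3 for H2-Eb1 (11.8) and replicate 5 for Suv39h2 (3.68), in CPM. In liver benzene, replicate 4 was far from the others for Cd5l (60.2), Pck1 (1840), Cyp2e1 (6960), Cyp2f2 (1040), Ephx1 (524), Gstt1 (171) and Gstm2 (84.5), replicate 3 for Nr4a1 (6.24) and Nipal1 (2.34), and replicate 2 for Hmox1 (20.7). In lung air, replicate 5 was far from the others for Pvalb (230), Myh4 (47.2), Cyp1a1 (131), Cdkn1a (58.8), Stip1 (112), Ighm (351), Lrg1 (93.3), Cyp2f2 (946), Cyp2b10 (269), Ephx1 (123) and Gstt1 (20.8). It also stood apart in genes without a read (894), in mitochondrial share (0.658%) and in the share of the 10 most abundant genes (17.6%). In lung benzene, replicate 1 was far from the others for Myl2 (0.306) and replicate 6 for Tnnt1 (1.84) and Cyp2b10 (336).

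The change of benzene over air libraries, here called the response, differed between liver and lung for these genes by the test of the difference. Values are liver minus lung on the log2 scale. The test does not part exposure from added tissue or from the source of the RNA. The liver response was lower for Perp (-1.50), Dsc2 (-2.19), Tgm1 (-2.33), Gjb2 (-1.90), Fabp5 (-1.73), Arg1 (-2.55), Bcl6 (-1.03), Cyp2b10 (-0.61), Nipal1 (-1.97), Malat1 (-1.62), Suv39h2 (-1.46), Gstm2 (-0.64) and Pck1 (-1.04). It was higher for Ighm (1.73), Tnnt1 (2.51), H2-Eb1 (1.29), H2-Ab1 (1.39), H2-Aa (1.16), Dnaja1 (0.74), Cd74 (1.39), Cd5l (1.56), Igkc (1.78), Hspa1b (1.00), Acta2 (0.94), C1qb (1.00), Selenbp2 (1.06), Gadd45g (1.39), Ctss (0.73), Lrg1 (0.59), Cyp1a1 (1.37), Hmox1 (0.66), Nr4a1 (1.00), Stip1 (0.48) and Marco (0.78).

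Other splits of the libraries tested the counts. They measure the spread between libraries, so where the libraries of a group share 1 source of RNA, a difference between 2 sources is not excluded. Among the splits drawn, only the real one called as many liver genes (1 of 100 splits as large, 186 against a highest other of 125). The same held for the lung genes (1 of 100, 891 against 0) and the difference (1 of 100, 159 against 110). Chance in how the libraries were grouped is thus unlikely for these counts, though it is not excluded. The liver split with 125 genes differed from the real one only by an exchange of air replicate 1 and benzene replicate 4. For the lung lists 1 of 100 splits passed as many, but the count was 25 against a highest other of 24. Not every split was drawn, so that margin is too small to exclude chance. Nor can chance be excluded for the liver lists, where 8 of 100 splits passed as many (13 against a highest other of 17).

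In lung, the use of 52 immunoglobulin variable genes was alike within each group and unlike between them, with air replicate 5 left out. The mean correlation across genes was 0.767 within groups (0.648 to 0.882) and 0.18 between them (0.0683 to 0.280), a gap of 0.587 that 1 of 462 splits reached (exact p = 0.00217, highest other 0.394) and 3 of 1000 lists of genes of like level. How alike variable gene use is among separate animals was not measured here. If it differs among them, a candidate explanation is that the libraries of each group share 1 RNA source, such as pooled or divided tissue. Replicates of 1 group still differed beyond counting noise (chi-square over degrees of freedom 4.12 to 13.04 in lung air and 2.15 to 17.85 in lung benzene). That is more than plain division of 1 RNA without added library spread gives. In lung benzene the closest pairs were 1 with 3 (2.15), 2 with 4 (3.025) and 5 with 6 (3.67), and other pairs began at 5.88. In lung air, replicates 1, 2 and 3 (4.12 to 5.47) and 4 with 6 (4.81) were closer than other pairs (from 7.97). The source of these subgroups was not tested. The median squared coefficient of variation of immediate early genes within groups, above counting noise, was at most 1.14 times that of genes of like level. That highest ratio was in liver benzene, with 1.00 in lung air and 1.05 in lung benzene. Separate animals handled alike would also give such ratios. Whether exposure changed the usage cannot be told apart from the source in this design: 5 of 41 tested variable genes passed, all lower; with a shared source the p-values measure technical spread.

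In benzene lungs, squamous genes rose and muscle genes changed unevenly. Of squamous genes not looked at before, 27 of 30 rose (90%). Tissue with stratified squamous epithelium in the RNA, such as adjoining upper airway or oesophagus, may account for them. Of the 42 tested squamous genes, 34 had a mean of at least 1 in air lungs and 3 are in another list. Krt4 spanned 1320 to 1450 CPM over 6 benzene libraries. The median coefficient of variation was 12.5% over the 40 members with a benzene mean of at least 5. Added tissue would thus have to make up a like share of each benzene library. Airway epithelium that became squamous on exposure cannot be told apart from added tissue, since both raise the list (median log2 2.55); the club and ciliated cell lists, seen before this test was set, had mean log2 changes of -0.36 and -0.20 (adjusted p = 0.0555, which misses the threshold, and 0.0424 with an estimated correlation). A smaller piece of 1 muscle was tested first on the 5 most abundant muscle genes. Of these, 0 lay more than 1 log2 above the median fall of -1.02, the bound set for it. Acta1, 1 of the 5, lay just short of that bound and did not pass the threshold (-0.089 ± 0.067, adjusted p = 0.439). The count of 0 is thus weak support. A second bound, set after that result and the members' values had been seen, found 3 genes whose interval lay more than 1 log2 from that median, among them Actn3, which rose by 1.20 ± 0.0982, and Myh2 (-6.00), so 1 muscle in a smaller amount does not account for all of them.

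Lung air replicate 5 lay far from the other air lungs. Replicate 5 had a median position of -0.0117 between the air mean (0) and benzene mean (1) over 269 genes. This argues against a lung with the changes of the benzene lungs under an air label. The 269 genes were called without it with a log2 change of at least 1, and squamous and muscle genes are among them. A benzene lung that lacked the squamous and muscle changes could also lie near 0, so its exposure is not settled. Lower RNA or library quality stays open, with a Spearman rho across genes of -0.175 for length and 0.0093 for GC content against up to 0.155 and 0.28 in size in the other air lungs. RNA from another animal or source than the other 5 air lungs is a candidate explanation: 40 of 52 variable genes had no read in it (76.9%), against a median of 21.2% and a highest of 42.3% in lists of genes of like level.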

How the results depend on the processing

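Array weights, robust eBayes, edgeR, TMM scaling and the tests without lung air replicate 5 were chosen after the data were seen. Of 35 liver genes printed as past the threshold, 28 kept their call and direction in every alternative in which they could be tested; 5 lost it without 1 library and 7 under another setting. Of these 35, 23 could be tested in each of 23 alternatives, and 16 of them kept it; 12 are not in the lung table or filter and so not in the fit of all 22 libraries, and 3 fell under the filter without 1 library. In lung 35 of 42 kept it where tested. Of these 42, 17 could be tested in each of 26 alternatives, and 12 of them kept it; 25 are not in the fit of all 22 libraries and 3 fell under the filter without 1 library. The minimum change was applied to counts alone. Of the differences between tissues, only the 11 named in the Results were run under 28 alternatives, and 11 of 11 kept it. The other differences listed as flagged were not run under them, so their stability is not known. Of passing lists, 8 of 13 kept it in liver and 8 of 25 in lung. No printed gene or list past the threshold changed direction where tested. Lung Cyp2e1, not past the threshold, passed by DESeq2 (adjusted p = 0.0209), with all 22 libraries in 1 fit (0.0395), with array weights (5.02e-05) and, without air replicate 5, by limma (7.62e-05) and edgeR (5.5e-05). RLE scaling is the deposited scaling within each tissue, so there that alternative changed nothing and says nothing about stability.

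The liver count of 186 was 316 by DESeq2, 461 with array weights, 74 with all 22 libraries in 1 fit (fewer genes tested, shared spread), 26 with a log2 change of at least 1, and 98 to 271 without 1 library. The lung count of 891 was 1669 by DESeq2, 3215 with array weights, 489 with all 22 libraries in 1 fit, 286 with a log2 change of at least 1, 502 to 2284 without 1 library and 2256 by edgeR without air replicate 5. A replicate block gave 414 in lung. It ended the calls of Cdkn1a, Nqo1, Mki67, Tgfb1, Trp53inp1 and Cd74 in lung (adjusted p from 0.0515 to 0.102) and of Me1 in liver (0.0654). Residuals of libraries with 1 number correlated at -0.13 to 0.19 in liver and -0.36 to 0.098 in lung, so the numbers are not known to pair samples. With an estimated correlation the list counts were 8 in liver and 11 in lung, and 10 in lung without air replicate 5 as well. The difference count of 159 (81 higher in liver, 78 lower) was 377 by DESeq2 (245 and 132), 144 by edgeR (88 and 56), 125 with a replicate block by voom (79 and 46), 163 with RLE factors per tissue over the genes in both tables, and 88 to 327 without 1 library. The overlap of 5 was 34 at an unadjusted p of 0.01, 15 by DESeq2 and 19 without lung air replicate 5. Except as stated, the cause was not tested.

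In lung, Cyp2f2 (0.01, not past the threshold) turned to -0.10 by DESeq2, -0.10 by edgeR, -0.23 with array weights, -0.27 by edgeR without air replicate 5, and ran from -0.28 to 0.086 without 1 library. Gstt1 (0.15, not past the threshold) turned to -0.13 with array weights and -0.19 by edgeR without air replicate 5, and ran from -0.19 to 0.23 without 1 library.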

Other observations

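In liver, 4 of 21 genes of bile acid synthesis and transport rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.191). Of 28 periportal hepatocyte markers, 3 rose and 6 fell, or 4 and 12 adjusted over the list alone (list adjusted p = 0.132), and of 39 phase II conjugation enzymes 4 rose and 4 fell, or 8 and 8 adjusted over the list alone (list adjusted p = 0.891).

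In lung, 5 of 22 smooth muscle and pericyte markers fell and 1 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.0997 with an estimated correlation), with the smooth muscle actin gene Acta2 from 488 ± 63.9 to 326 ± 21. Of 19 adipocyte genes 5 fell and 1 rose, or 7 and 2 adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). Of 50 oxidative phosphorylation genes 5 fell, or 11 adjusted over the list alone (adjusted p = 0.239 with an estimated correlation). Of 24 cholesterol synthesis genes 1 rose, or 3 adjusted over the list alone, and of 20 acute phase proteins 4 fell, or 6 adjusted over the list alone (adjusted p = 0.111 and 0.113 with an estimated correlation). The oxidative phosphorylation list also missed the threshold by the exact permutation test of list means (adjusted p = 0.0693). Its means in benzene replicates 2 and 4 (7.12 and 7.16) lay among those of the air lungs other than replicate 5 (7.07 to 7.17). Benzene replicates 1, 3, 5 and 6 were lower (6.66 to 6.77), and air replicate 5 was at 7.91.

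Another 5 lung lists lost their call without 1 library and with an estimated correlation. Ribosomal proteins missed it without air replicate 5 (adjusted p = 0.0772) and with an estimated correlation (0.601), by fry (0.329) and by exact permutation (0.368). Proteasome subunits missed it without air replicate 5 (0.162) or benzene replicate 1 (0.0919) or 3 (0.0828), with an estimated correlation (0.601), by fry (0.279) and by exact permutation (0.24). Mitochondrially encoded transcripts missed it without air replicate 2 (0.077) or 3 (0.0818), with an estimated correlation (0.226), by fry (0.258) and by exact permutation (0.161). Fatty acid oxidation genes missed it without air replicate 4 (0.0575) and with an estimated correlation (0.0665), and alveolar type I markers without air replicate 1 (0.0661), 2 (0.0565), 3 (0.0818) or 6 (0.0501) and with an estimated correlation (0.0937).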
